A study of Arabidopsis thaliana with 35 samples.

How the data were processed

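Poly(A) RNA of mature pollen of Arabidopsis thaliana (ecotype Col0) was sequenced in 35 libraries. The labels name 7 genotypes: wild-type, mbd5 mbd6, sln, acd15, acd21, acd15 acd21 and acd15 acd21 sln. Each had 5 replicates, of which replicates 1 and 2 belonged to batch 1 (14 libraries) and replicates 3 to 5 to batch 2 (21 libraries), so that every genotype had 2 libraries in batch 1 and 3 in batch 2. Per the labels' protocols, pollen was collected in Galbraith buffer, RNA was extracted with a Direct-zol kit with DNase I digestion on the column, and libraries were made with the Illumina TruSeq Stranded mRNA protocol. The labels do not say whether replicates came from separate plantings, so p-values measure the spread between these samples, part of which may be technical.

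The authors deposited, for each library, a table of whole-number read counts per feature, which was used as deposited. Per the submitters' processing notes the tools were Trim Galore, STAR, HTSeq and deepTools and the genome build was TAIR10. Their versions and settings, the strand setting of the counting and the source of the features that are not in the Arabidopsis annotation are not given in the sources used here. Each table held 66429 features: 34490 nuclear genes, 268 organelle genes, 23488 transposable elements, 6214 noncoding and 1950 coding transcripts with identifiers of an added annotation (such as novel_Chr3_noncoding_833), and 19 merged loci. A further 5 summary lines of HTSeq stayed out of library sizes and tests. Reads in no feature were 0.217 to 0.999% of counted plus unassigned reads (median 0.580%) and ambiguous reads 0.108 to 0.135%. The lines for reads that did not align uniquely, did not align or had low quality were 0 in every library, so the tables do not show how many reads with several alignments were set aside. Values of transposable elements, pseudogenes and members of multigene families are uncertain for that reason, and those of overlapping or antisense genes because the strand setting is not given. Total counts were 9267958 to 22208090 per library (median 13847738). Nuclear genes took 96.6 to 97.4% of counts, and the most abundant feature at most 1.15%.

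Gene symbols, gene classes and coordinates came from a RefSeq table of assembly TAIR10.1, which matched 34395 of the nuclear gene identifiers. It holds no positions for the added transcripts or the transposable elements. Features were classed as transposable elements by identifier alone (such as AT3TE51735). A transposable element gene with a gene identifier would therefore be counted in its RefSeq class, pseudogenes included. How many pseudogenes are of this kind was not examined.

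Differences were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood fit and test, robust dispersions, TMM scaling), in 1 fit of all 35 libraries with a term for each genotype and a term for batch. Features passed filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 12106 features. Among these were 9849 protein-coding genes, 258 transposable elements, 153 pseudogenes, 280 noncoding RNA genes, 1219 added noncoding and 318 added coding transcripts. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all 12106, with no minimum fold. Errors of log2 fold changes are standard errors of the same fit, and errors of CPM (counts scaled to library size, prior count 2 on the log2 scale) and of percentages are standard deviations over libraries. The comparisons were each of the 6 mutants with wild-type, 8 comparisons between mutants, and 2 interaction terms, acd15 by acd21 and sln by acd15 acd21, each testing a departure from adding log2 effects. Where all wild-type libraries had 0 counts, a fold was computed against 3 counts over the group and printed with "at least". It leaves out the error of the mutant counts, so that the lower end of an exact 95% counting interval can lie below it. Where wild-type libraries held 1 to 3 counts in all, a ratio with its exact 95% counting interval is given. Intervals cover counting error only, and the floor covers that of the wild-type counts only.

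Gene lists fixed before the data were examined were tested against all other tested features with camera in limma 3.58.1 (inter-gene correlation preset to 0.01, prior count 1), adjusted over all lists and comparisons with wild-type. They were compared with camera with an estimated correlation and with fry, both for members that move 1 way and for members that move either way; the latter called the transposable elements in all 6 mutants and the sperm cell and vegetative cell lists in sln, and no other list. The lists were DNA methylation machinery (9 of 17 members tested), DNA demethylation genes (4 of 7), other MBD family genes (5 of 9), post-transcriptional silencing genes (3 of 10), heat shock genes (10 of 19), DNA damage response genes (7 of 8), stress and defence genes (5 of 18), vegetative cell and pollen tube genes (33 of 34), sperm cell genes (14 of 15), green tissue genes (14 of 17) and all transposable elements (258 of 23488). The targeted genes (2 of 5 tested), methylation-silenced or imprinted genes (2 of 16), tapetum genes (1 of 19) and floral organ genes (1 of 5) were too thinly measured for a set test. The percentage of counts in transposable elements, and other percentages of libraries, were compared with an exact permutation test that shuffled libraries regardless of batch. Enrichment of feature classes among called features used Fisher's exact test with the 12106 tested features as background, which treats features as independent.

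Before the data were examined, the genes to be named were set by rule: the 5 targeted genes; for mbd5 mbd6 the 10 largest higher and 5 largest lower fold changes among called features with a mean log2 CPM of at least 0 and no overlap between genotypes within a batch, with the 5 largest higher annotated genes; for each other mutant the 5 largest higher and 3 largest lower by the same rule; the 10 called higher and 5 called lower in all 6 mutants with the largest mean change; up to 4 called members of each list per comparison, with FWA, SDC and HSP101 in any case; and the 3 smallest adjusted p of each comparison between mutants and of each interaction.

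The test was checked on simulated counts with changed features at known folds, drawn for the 12106 features of mbd5 mbd6 against wild-type. It called 46 of 65 features changed 1.5-fold (70.8%), 67 of 73 changed 2-fold (91.8%) and 61 of 62 changed 4-fold (98.4%). Of its 193 calls 7 were false (3.63%), and comparisons without the changed genotype had 0 calls. With camera in limma, the adjusted p of a simulated raised list was 5.88e-32 and that of an unchanged list 0.846. Simulated features were drawn independently and without a batch effect. The check therefore cannot show how the list test behaves with correlated members, such as the heat shock genes (estimated correlation 0.671). Replicates were compared before they were averaged: the 70 pairs of libraries of 1 genotype had a chi-square per degree of freedom of 2.70 to 26.4 over features with at least 20 counts, so that no pair agreed within sampling noise.

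Alternatives set before the data were examined were relative log expression scaling (RLE), no low-count filter, DESeq2 1.42.0, no batch term, the replicate number as a block, each batch alone, fits of only the groups compared, a 2-fold minimum, and leaving out each library in turn. Alternatives added after the data were seen were the percentage of reads in no feature as a covariate, all replicate 4 libraries left out, 3 libraries that stood apart on the second principal component left out, the 3 libraries with the lowest percentage of reads in no feature left out, and edgeR dispersions of the earlier quasi-likelihood method. Tables were joined and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Sequencing reads, splicing and protein levels were not analysed here.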

Results

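Transcript levels were measured by stranded poly(A) RNA-seq in mature pollen, the male gametophyte that carries a vegetative cell and the sperm cells, of 7 Arabidopsis genotypes with 5 libraries each. MBD5 and MBD6 are proteins with a methyl-CpG-binding domain that recognise methylated DNA, SLN (SILENZIO) is a J-domain protein that works with them, and ACD15 and ACD21 are small heat-shock-like proteins with an alpha-crystallin domain. The study's title names these proteins together with the silencing of genes and transposable elements, so each mutant was set against wild-type and the mutants against each other. The 35 libraries held 9267958 to 22208090 counts (median 13847738), and 12106 features were abundant enough to test. All adjusted p-values of single features are from the quasi-likelihood test of edgeR with n = 5 libraries per genotype.

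The transcripts of the mutated genes were examined first. MBD6 (AT5G59380, chromosome 5, 23952132 to 23953707 in TAIR10.1) had 0 to 2 counts in each mbd5 mbd6 library against 8 to 16 in each wild-type library, where its level was 0.815 ± 0.147 CPM (SD, n = 5), and it was called lower in mbd5 mbd6 (adjusted p = 2.83e-07). In the other 5 mutants its log2 change was between -0.03 and 0.42 and was not called. SLN (AT5G37380, chromosome 5, 14816734 to 14819346) stood at 4.51 ± 0.286 CPM in wild-type and 0.259 ± 0.196 CPM in sln, 16.0-fold lower (adjusted p = 6.00e-19), and changed by -4.23 ± 0.25 in acd15 acd21 sln (adjusted p = 3.18e-18). MBD5 (chromosome 3, 17148232 to 17149597), ACD15.5 (AT1G76440, chromosome 1, 28682084 to 28683785) and ACD21.4 (AT1G54850, chromosome 1, 20454389 to 20456220) had at most 4 counts in any library, wild-type included, so their transcripts could not check the acd15 and acd21 labels. The labels give no gene identifiers, and those used for SLN, ACD15.5 and ACD21.4 come from background knowledge. The low counts of AT5G37380 in sln and acd15 acd21 sln are a check of the first of them. None was possible for the ACD genes.

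The comparison of mbd5 mbd6 with wild-type asked which transcripts are kept low by the methyl-binding proteins in pollen. FWA (AT4G25530, chromosome 4, 13038360 to 13042464), an imprinted homeodomain gene silenced by DNA methylation, was 13.9-fold higher, at 8.55 ± 0.875 CPM against 0.605 ± 0.245 (log2 3.80 ± 0.18, adjusted p = 5.24e-22). The pectate lyase family gene AT1G67750 (chromosome 1, 25401514 to 25403595) was 123-fold higher, at 553 ± 26.5 CPM against 4.47 ± 0.994 (log2 6.94 ± 0.08, adjusted p = 2.35e-46). The transposable element AT3TE51735 rose from 0.134 CPM to 44.4 ± 3.21 (log2 8.27 ± 0.19), and AT1G36360 from 0.0756 CPM (log2 6.39 ± 0.41). In all, 492 features were higher and 171 lower, of which 271 and 29 changed at least 2-fold. The higher features included 79 transposable elements, 45 pseudogenes, 109 added noncoding and 44 added coding transcripts, and 202 protein-coding genes.

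Several features without a count in wild-type were abundant in mbd5 mbd6. The added noncoding transcript novel_Chr3_noncoding_833 was at least 208-fold higher, the merged locus novel_Chr2_merged_2 at least 128-fold, the pseudogene AT2G11170 (chromosome 2, 4433758 to 4438035) at least 78.7-fold, novel_Chr5_noncoding_671 at least 77.0-fold and the transposable element AT2TE03160 at least 58.2-fold. The genes AT4G06608 and AT3G30230 were at least 24.7-fold and 21.2-fold higher. These folds take a floor of 3 wild-type counts and leave out the error of the mutant counts. The lower ends of the exact 95% counting intervals were 169, 103, 63.5 and 62.1 for novel_Chr3_noncoding_833, novel_Chr2_merged_2, AT2G11170 and novel_Chr5_noncoding_671. With 1 count in wild-type, novel_Chr4_coding_54 had a ratio of 621 (95% counting interval 111 to 24584). The median log2 change of the higher transposable elements was 1.92 and that of the higher pseudogenes 2.66, against 0.47 for the higher protein-coding genes. Transposable elements were 16.1% of the higher features, an odds ratio of 12.2 (95% interval 9.08 to 16.3) over the tested features by Fisher's exact test, with p = 2.49e-48. Features next to each other are not independent, so the interval and p may overstate the certainty. The odds ratio was 10.7 for pseudogenes and 0.142 for protein-coding genes. Pseudogenes may include transposable element genes, which were not told apart from the others. Elements without wild-type counts could pass the low-count filter only through mutants where they were high, so the size of the odds ratio may depend on the filter. Without the filter the enrichment kept its call in all 6 mutants.

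Features lower in mbd5 mbd6 were mostly protein-coding (132 of 171), as were the features tested (9849 of 12106). Of the tested protein-coding genes 1.34% were lower, against 1.94% of transposable elements and 2.61% of pseudogenes. RIF10 (chromosome 3, 919362 to 925372), an organelle polyribonucleotide nucleotidyltransferase, was 3.41 CPM in wild-type and fell by 1.51 ± 0.21 on the log2 scale (adjusted p = 6.25e-07). The fibrillin gene AT4G22240 (chromosome 4, 11765803 to 11767422) changed by -1.49 ± 0.32 (adjusted p = 9.03e-04), novel_Chr5_noncoding_249 by -1.52 ± 0.31 and AT2G06890 by -1.52 ± 0.33, whereas AT2G06890 was higher in acd15, acd21 and acd15 acd21 (1.76, 1.99 and 1.80). AT4G22240 and novel_Chr5_noncoding_249 were not called in batch 1 alone, and AT2G06890 in neither batch alone (adjusted p = 0.0815 and 0.0664). The transposable element AT4TE19655 changed by -2.34 ± 0.67 (adjusted p = 0.0345), a call that ended without wild-type library 1, 3, 4 or 5 or mbd5 mbd6 library 2 or 5 (adjusted p = 0.0566 to 0.145) and in each batch alone (0.384 and 0.230).

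The share of all counts in transposable elements sums over the class. Abundant elements weigh most in it, so it does not show how many elements responded. It was 0.292 ± 0.0162% in wild-type, 0.395 ± 0.0312% in mbd5 mbd6, 0.403 ± 0.0347% in sln, 0.433 ± 0.0220% in acd15, 0.40 ± 0.00913% in acd21, 0.424 ± 0.0325% in acd15 acd21 and 0.377 ± 0.0318% in acd15 acd21 sln (SD, n = 5 each). Every library of each mutant lay above every wild-type library. The exact two-sided permutation p was 0.00794 in each of the 6 comparisons (adjusted 0.00794), the smallest possible with libraries shuffled regardless of batch. The 6 comparisons share the wild-type libraries. The ratios to wild-type were 1.35, 1.38, 1.48, 1.37, 1.45 and 1.29 in the same order. In batch 1 the differences were 0.0923, 0.0940, 0.136, 0.125, 0.120 and 0.0872 percentage points, and in batch 2 0.111, 0.123, 0.144, 0.0964, 0.140 and 0.0839.

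**Figure D1:**
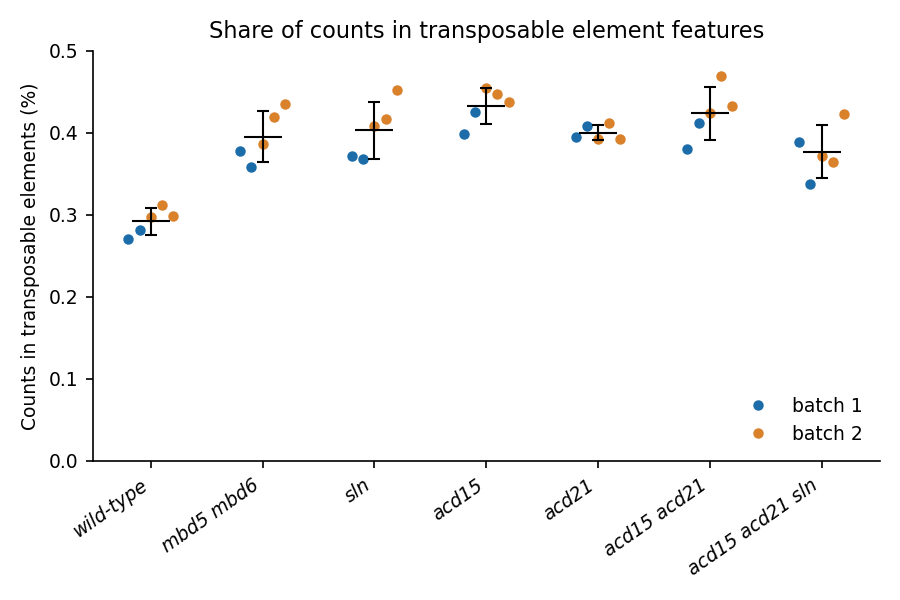
Percentage of all counts in transposable elements in each of the 35 libraries, by genotype and batch, with the mean and SD of 5 libraries per genotype. Every mutant mean, from 0.377 to 0.433%, lies above the wild-type mean of 0.292%.

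The sln mutant was compared with wild-type to ask which transcripts need the J-domain protein to stay low. FWA was 9.86-fold higher (log2 3.30 ± 0.19, adjusted p = 7.90e-19), at 6.07 ± 0.848 CPM, and the pseudogene AT3G31470 (chromosome 3, 12818516 to 12820597) rose from 6.34 ± 1.74 to 119 ± 6.40 CPM (log2 4.25 ± 0.09). AT1G67750 was 2.19-fold higher, at 9.89 ± 0.969 CPM (log2 1.13 ± 0.11, adjusted p = 3.37e-11), and AT3TE51735 reached 8.26 ± 1.29 CPM (log2 5.83 ± 0.26). The syntaxin gene SYP122 (chromosome 3, 19425632 to 19427230), at 0.105 ± 0.0934 CPM in wild-type, was not called (log2 0.02 ± 0.75, adjusted p = 0.993). Among features without wild-type counts, novel_Chr2_merged_2 was at least 120-fold higher, novel_Chr5_noncoding_671 at least 68.8-fold and novel_Chr3_noncoding_833 at least 33.4-fold; novel_Chr4_coding_54 had a ratio of 551. In sln 569 features were higher and 195 lower, with 80 transposable elements, 53 pseudogenes, 99 added noncoding transcripts and 283 protein-coding genes among the higher ones. Besides SLN itself (AT5G37380), novel_Chr4_noncoding_275 changed by -1.69 ± 0.21 and AT1G48953 by -1.68 ± 0.23. With DESeq2 the split was 422 higher and 258 lower, and without sln library 5, the deepest of the series, 90 features were lower.

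Mutants of the alpha-crystallin proteins were compared with wild-type to ask what ACD15 and ACD21 keep low, alone and together. FWA was 15.9-fold higher in acd15, 16.9-fold in acd21 and 13.8-fold in acd15 acd21 (log2 3.99 ± 0.17, 4.08 ± 0.17 and 3.79 ± 0.18). AT1G67750 reached 662, 728 and 673 CPM (log2 7.20, 7.34 and 7.22, each ± 0.08), SYP122 rose by 6.82 ± 0.25, 6.90 ± 0.25 and 7.08 ± 0.24 on the log2 scale, and AT3TE51735 by 9.10, 9.10 and 9.04. The floor-based folds of novel_Chr3_noncoding_833 were at least 458, 257 and 319, those of novel_Chr2_merged_2 at least 176, 122 and 197, and those of AT2G11170 at least 98.3, 72.6 and 93.4. In acd15 acd21, novel_Chr3_coding_275 was at least 95.6-fold higher, and novel_Chr4_coding_54 had ratios of 1020, 670 and 1052. Higher and lower features numbered 428 and 125 in acd15, 399 and 149 in acd21, and 449 and 153 in acd15 acd21, with 89, 78 and 88 transposable elements and 54, 46 and 56 pseudogenes among the higher ones.

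Features lower in these 3 mutants were led by a transcription factor gene. NAC105 (AT5G66300, chromosome 5, 26479766 to 26481528), a member of the NAC family linked to xylem vessel formation, was 5.94 ± 0.700 CPM in wild-type and 0.308, 0.0778 and 0.197 CPM in acd15, acd21 and acd15 acd21 (log2 -4.29 ± 0.23, -6.29 ± 0.34 and -5.02 ± 0.27). In mbd5 mbd6, sln and acd15 acd21 sln the same gene was higher than in wild-type, at 27.0, 25.8 and 27.2 CPM (log2 2.18, 2.12 and 2.20, each ± 0.10). The methyltransferase family gene AT5G37970 (chromosome 5, 15123089 to 15124435) changed by -2.05 ± 0.17, -3.77 ± 0.25 and -3.97 ± 0.24, and the added transcript novel_Chr5_coding_282 by -2.08 ± 0.26, -2.18 ± 0.30 and -2.52 ± 0.29. The pectin methylesterase inhibitor family gene AT1G62760 changed by -2.25 ± 0.24 in acd15 and -1.51 ± 0.24 in acd21, while in acd15 acd21 its change of 0.45 ± 0.16 was not called (adjusted p = 0.112).

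In acd15 acd21 sln, FWA was 16.7-fold higher (log2 4.06 ± 0.17), AT1G67750 stood at 623 CPM (log2 7.11 ± 0.08), SYP122 rose by 6.62 ± 0.26 and AT3TE51735 by 8.83 ± 0.17. novel_Chr3_noncoding_833 was at least 218-fold higher, novel_Chr2_merged_2 at least 81.7-fold, AT2G11170 at least 66.5-fold and AT2TE03160 at least 58.7-fold. The comparison called 463 features higher and 289 lower, among them 76 higher transposable elements, 52 pseudogenes, 99 added noncoding transcripts and 178 lower protein-coding genes. After SLN (AT5G37380), the features with the largest decreases were novel_Chr3_noncoding_1248 (-2.09 ± 0.62, adjusted p = 0.0403) and RIF10 (-1.80 ± 0.23). The call of novel_Chr3_noncoding_1248 ended without wild-type library 2, 3 or 4 or triple mutant library 2, 3, 4 or 5 (adjusted p = 0.0508 to 0.158) and in batch 1 alone (0.841). The lower features included 63 added noncoding transcripts. Without triple mutant library 1, 519 features were lower, with the percentage of reads in no feature as a covariate 186, without the 3 libraries apart on the second principal component also 186, and with only the groups compared in the fit 143 (and 284 higher). The percentage of reads in no feature was 0.447 ± 0.266% in this genotype, 0.492 ± 0.224% in acd15 acd21 and 0.762 ± 0.169% in wild-type. These differences did not pass an exact permutation test that shuffled libraries regardless of batch (p = 0.0635 and 0.0714, adjusted 0.214). Over the 35 libraries, with genotype and batch means removed, the mean level of 1161 uncalled noncoding features rose with this percentage (Pearson's r = 0.915, Spearman's rho = 0.922, permutation p = 1e-05 for each, the smallest possible; r = 0.954 in batch 1 and 0.838 in batch 2).

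**Figure D2:**
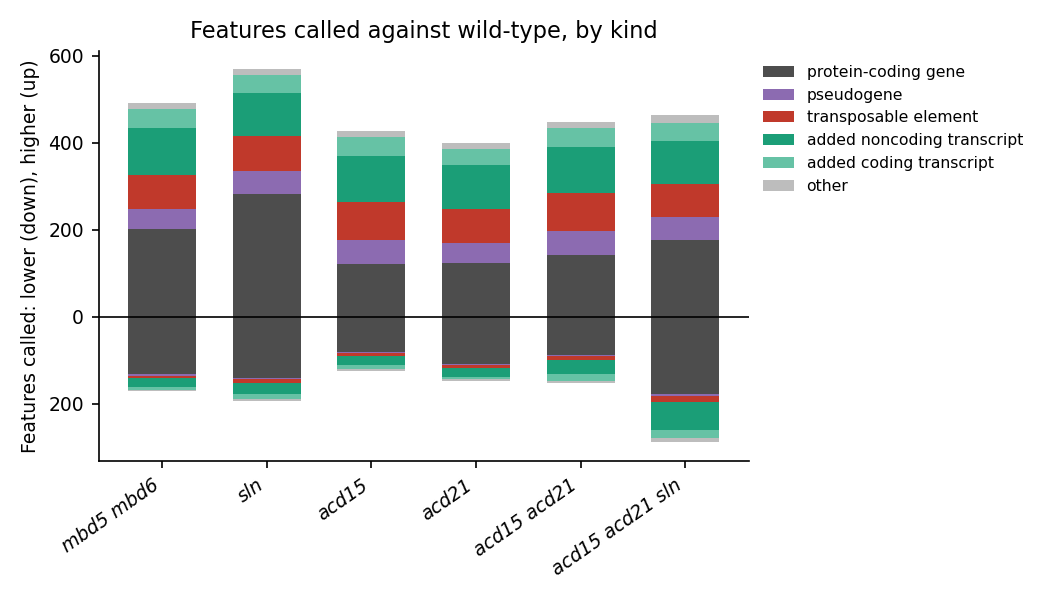
Number of features called higher (above 0) and lower (below 0) than wild-type in each mutant, by class of feature, at an adjusted p under 0.05 (edgeR, n = 5 per genotype). Transposable elements made up 76 to 89 of the higher and 5 to 14 of the lower features of a mutant.

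Of the 952 features higher in at least 1 mutant, 433 were higher in only 1, and of the lower features 402 were lower in only 1. The 260 features higher in all 6 mutants included 62 transposable elements, 76 added noncoding and 29 added coding transcripts, 41 pseudogenes and 43 protein-coding genes. FWA, AT1G67750, AT3TE51735, AT3G31470, AT2G11170 and novel_Chr3_noncoding_833 belonged to this group, as did the added transcripts novel_Chr2_noncoding_225, novel_Chr2_coding_146 and novel_Chr2_noncoding_372. The 19 features lower in all 6 mutants included AT5G37970, AT2G07085 (-1.33 ± 0.29 in mbd5 mbd6, -2.51 in acd15), RIF10, novel_Chr4_noncoding_275 and AT1G48953. In batch 1 alone, where 2 libraries per genotype entered, AT2G07085, novel_Chr4_noncoding_275, AT1G48953 and AT5G37970 lost part of these calls, and AT2G11170 its call in sln (adjusted p = 0.416). Odds ratios of transposable elements among higher features were between 10.4 in sln and 17.9 in acd15, and those of pseudogenes between 10.7 in mbd5 mbd6 and 17.0 in acd15 acd21. Within batches the comparisons with wild-type called 192 (sln) to 272 (acd15) features higher in batch 1 and 330 (acd21) to 466 (sln) in batch 2.

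The log2 changes of the 6 mutants were compared over the 952 features, as a question of how far the genotypes share their targets. Across features, which are not independent replicates, Pearson's r of 2 mutants had a median of 0.959 (0.869 to 0.987) and Spearman's rho of 0.790 (0.706 to 0.891). These features were selected for a call in a mutant. Over all tested features the median was 0.907 for r and 0.586 (0.530 to 0.651) for rho. All comparisons used the same wild-type libraries: unchanged groups simulated against them gave a median r of 0.516, and with wild-type libraries split between the compared mutants the observed median was 0.912. The covariance of log2 changes was 3.17 against 0.0742 in the simulation. Pairs of mutants shared 309 to 359 higher features, where independent lists would share 14.1 to 23.1, and 45 to 77 lower features against 1.54 to 4.66. Between 0 and 7 features were called in opposite directions. With wild-type libraries split, pairs shared 223 to 293 higher features. acd15 and acd21 had the highest r (0.987), and pairs with sln the lowest (0.869 to 0.887).

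**Figure D3:**
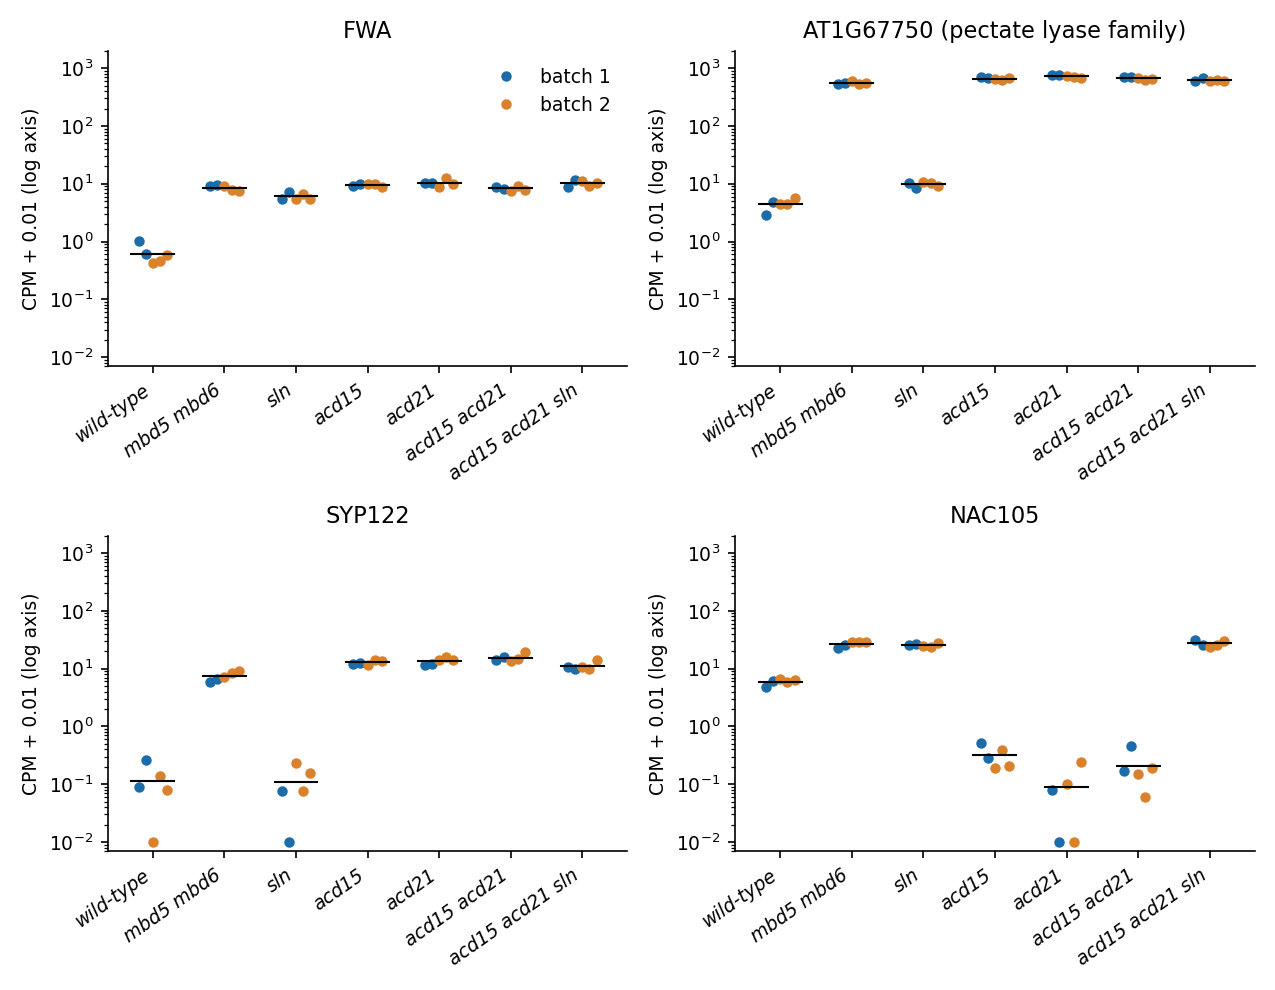
Levels of FWA, AT1G67750, SYP122 and NAC105 in each of the 35 libraries, in CPM plus 0.01 on a log axis, with a line at the mean of each genotype. AT1G67750 is at 4.47 CPM in wild-type, 9.89 in sln and 553 to 728 in the other mutants, and NAC105 is below wild-type in acd15, acd21 and acd15 acd21.

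The list of all 258 tested transposable elements was higher in each mutant by camera in limma, with adjusted p = 1.28e-19, 7.57e-16, 6.14e-24, 3.07e-22, 3.07e-22 and 4.05e-12 in mbd5 mbd6, sln, acd15, acd21, acd15 acd21 and acd15 acd21 sln. These calls held with an estimated correlation (adjusted p = 2.63e-05 to 0.00125). Over all features 79, 80, 89, 78, 88 and 76 members rose and 5, 10, 7, 7, 8 and 14 fell; adjusted over the list alone, 96, 89, 98, 89, 99 and 84 rose and 13, 15, 16, 13, 19 and 27 fell. The median log2 change was 0.13 to 0.23 and the mean 0.63 to 0.89. With no low-count filter, which added elements to a total of 2866 with any count, the list was not called in any mutant (adjusted p = 0.160, 0.838, 0.253, 0.125, 0.125 and 0.325).

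Heat shock genes as a list were lower by camera in limma in mbd5 mbd6, sln and acd15 acd21 sln (adjusted p = 0.0106, 0.00800 and 0.00300), with median log2 changes of -1.28, -1.29 and -1.46. None of these calls held: adjusted p = 0.777 with an estimated correlation for all 3. By fry in limma, which asks whether the members move 1 way and compares them with no other genes, adjusted p was 0.140, 0.145 and 0.0873. Of the 10 tested members, 0, 0 and 1 fell over all features and 3, 7 and 8 adjusted over the list alone; the list was not called in acd15, acd21 and acd15 acd21 (adjusted p = 0.968, 0.755 and 0.102). HSP101, a chaperone that resolves protein aggregates, was 4.02 ± 4.97 CPM in wild-type and had log2 changes of -2.06 ± 0.87, -1.77 ± 0.77 and -1.96 ± 0.86 that were not called. With the replicate number as a block HSP101 was called in mbd5 mbd6 and sln (edgeR, adjusted p = 0.0211 and 0.0477). That block also brought a call of the list in acd15 acd21 (camera in limma, adjusted p = 0.0400). The coactivator gene MBF1C changed by -0.91 ± 0.27 in acd15 acd21 sln (adjusted p = 0.0343), a call that ended without wild-type library 4 or 5 or triple mutant library 2, 3, 4 or 5 (adjusted p = 0.0530 to 0.181) and in each batch alone (0.798 and 0.0910). In wild-type the mean log2 level of the list was 1.91 higher in replicate 4 than in the other batch 2 libraries, and in the mutants 0.08 to 1.42 higher. With all replicate 4 libraries left out the median log2 changes of the 9 members then tested were -0.37, -0.59 and -0.81 in mbd5 mbd6, sln and acd15 acd21 sln. The list was then not called in mbd5 mbd6 (adjusted p = 0.162, against 0.0487 and 0.00523 in the others), and with batch 1 alone in neither mbd5 mbd6 nor sln (0.435 and 0.0825).

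Genes of the vegetative cell and pollen tube were lower as a list in sln and acd15 (camera in limma, adjusted p = 0.00169 and 0.0169, median log2 changes -0.11 and -0.08). Adjusted p = 0.777 with an estimated correlation for both, and 0.123 and 0.241 by fry for members that move 1 way; for members that move either way fry gave 0.0259 in sln and 0.460 in acd15. The list was not called in batch 1 alone (0.220 and 0.0895) or in the other 4 mutants (0.0754 to 0.858), of which acd15 acd21 was called in batch 2 alone (0.0320). Members moved both ways: in sln the sugar transporter gene STP6 was higher (0.75 ± 0.16, adjusted p = 0.00207), as was the pollen tube transcription factor gene MYB97 (0.19 ± 0.05, adjusted p = 0.0167), and AGL65 was lower (-0.17 ± 0.05, adjusted p = 0.0127). BUPS1 (AT4G39110), a receptor kinase of pollen tube integrity, rose by 0.42 ± 0.07 in mbd5 mbd6 (adjusted p = 2.25e-05). Over all features the list had 1 higher member in mbd5 mbd6, and 2 higher and 1 lower in sln, the same numbers as adjusted over the list alone. MYB97 was not called without wild-type library 2 or sln library 4 or 5 (adjusted p = 0.0502 to 0.0895), nor AGL65 without wild-type library 2 or 3 or sln library 4 (0.0564 to 0.0785). In batch 1 alone STP6 was not called (0.491), and in neither batch alone were MYB97 (0.423 and 0.123) and AGL65 called (0.602 and 0.0707).

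Sperm cell genes were not called as a list in any mutant (camera in limma, adjusted p = 0.184 to 0.986), except in acd15 acd21 with no low-count filter (0.0297). By the test of fry in limma for members that move either way the list was called in sln (adjusted p = 0.00258). DMP9 (DAU2), a sperm membrane protein gene, was higher by 0.20 in mbd5 mbd6, 0.20 in sln and 0.17 in acd15 acd21 (each ± 0.04; adjusted p = 6.45e-04, 5.41e-04 and 0.00546). The zinc finger genes DAZ1 and DAZ2, regulators of sperm formation, rose by 0.60 ± 0.12 and 0.56 ± 0.10 in sln, where GEX1 changed by -0.17 ± 0.05. In acd15 acd21 sln the sperm histone gene MGH3 changed by 0.19 ± 0.05, the gamete fusion gene HAP2 by -0.20 ± 0.06 and TET11 by -0.31 ± 0.10. With no batch term DMP9 was not called in any mutant, and in batch 1 alone neither DAZ1 nor DAZ2 was (adjusted p = 0.613 and 0.196), nor was MGH3 (0.752). DMP9 was not called in batch 2 alone in mbd5 mbd6 (0.144), in batch 1 alone in sln (0.371) and in either batch alone in acd15 acd21. GEX1, HAP2 and TET11 were called in neither batch alone (0.0922 to 0.740). GEX1 was not called without wild-type library 1, 2, 3 or 4 or sln library 2, 4 or 5 (adjusted p = 0.0529 to 0.225), MGH3 without wild-type library 4 or 5 or triple mutant library 4 or 5 (0.0579 to 0.138), HAP2 without wild-type library 4 or 5 or triple mutant library 1 or 3 (0.0780 to 0.160), and TET11 without wild-type library 2, 3 or 4 or triple mutant library 2, 3, 4 or 5 (0.0676 to 0.237). Adjusted over the list alone, 2 members were higher and 1 lower in mbd5 mbd6, 4 and 1 in sln, 1 and 0 in acd21, 2 and 0 in acd15 acd21, and 2 and 3 in acd15 acd21 sln.

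Among the lists of silencing factors, the DNA glycosylase gene ROS1 (DML1, chromosome 2, 15307907 to 15314807), which removes DNA methylation, was 2.30-fold higher in mbd5 mbd6 (adjusted p = 5.25e-04), 1.78-fold in sln (log2 0.83 ± 0.25, adjusted p = 0.0320) and 2.27-fold in acd15 acd21 (log2 1.18 ± 0.24, adjusted p = 4.93e-04). In acd15 acd21 sln its change of 0.75 ± 0.27 was not called. The sln call of ROS1 ended without wild-type library 1, 2 or 5 or sln library 1 or 5 (adjusted p = 0.0605 to 0.162) and with DESeq2 (0.0871). ROS1 was called in neither batch alone in mbd5 mbd6 (0.0556 and 0.0685) and sln (0.526 and 0.195), nor in batch 1 alone in acd15 acd21 (0.153). ROS1 was the 1 member of the DNA demethylation list called in these mutants; adjusted over the list alone 1, 2, 1 and 1 members were higher in mbd5 mbd6, sln, acd15 acd21 and acd15 acd21 sln. The histone methyltransferase gene SUVH5 rose by 0.29 ± 0.07 in acd15 (adjusted p = 0.00221) as the 1 called member of the DNA methylation machinery, though in neither batch alone (0.0723 and 0.20), with 1 member higher in mbd5 mbd6 and in acd15 adjusted over the list alone. AGO5, a germline Argonaute gene of the post-transcriptional silencing list, rose by 0.43 ± 0.11 in sln (adjusted p = 0.00941), but not without sln library 5 (adjusted p = 0.0661) or in batch 1 alone (0.617). That list had 2, 2, 1, 2 and 1 higher members adjusted over the list alone in mbd5 mbd6, sln, acd15, acd21 and acd15 acd21 sln. As lists, the methylation machinery (camera in limma, adjusted p = 0.362 to 0.986), demethylation genes (0.516 to 0.986), other MBD family genes (0.541 to 0.986) and post-transcriptional silencing genes (0.362 to 0.951) were not called in any mutant. With no low-count filter the methylation machinery was called higher in acd15 (adjusted p = 0.0428). In limma, fry called the post-transcriptional silencing list higher in mbd5 mbd6 (adjusted p = 0.0273).

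DNA damage response genes (camera in limma, adjusted p = 0.411 to 0.986), stress and defence genes (0.0608 to 0.755) and green tissue genes (0.181 to 0.994) were not called as lists in any mutant. The ribonucleotide reductase gene TSO2 changed by -0.15 ± 0.04 in acd15 (adjusted p = 0.0322) and -0.24 ± 0.04 in acd15 acd21 sln (adjusted p = 1.19e-04), and the DNA repair gene BRCA1 by -0.45 ± 0.10 in acd15 acd21 sln (adjusted p = 0.00131). The jasmonate synthesis gene LOX3 rose by 1.81 ± 0.47 (adjusted p = 0.0113) and the stress regulator gene ZAT12 (RHL41) by 0.50 ± 0.15 (adjusted p = 0.0426) in sln, and the Rubisco small subunit gene RBCS3B changed by -0.53 ± 0.08 in acd15 acd21 sln (adjusted p = 1.35e-06). LOX3 was not called without wild-type library 4 (adjusted p = 0.0590) or in batch 1 alone (0.937), TSO2 not in acd15 without wild-type library 1, 2, 3 or 4 or acd15 library 1, 3 or 5 (0.0603 to 0.125), and ZAT12 lost its call when any library but sln library 2 was left out (0.0505 to 0.307). Adjusted over the list alone, lower DNA damage genes numbered 2 in sln, 1 in acd15 and 2 in acd15 acd21 sln, higher stress genes 3 in sln and 1 in acd15 acd21 sln, and lower green tissue genes 1 each in sln and acd15 acd21 sln. In batch 2 alone neither BRCA1 (adjusted p = 0.179) nor TSO2 in acd15 acd21 sln (0.124) was called. In neither batch alone were TSO2 in acd15 (0.339 and 0.353) and ZAT12 called (0.797 and 0.0747). The stress list was called higher in sln with RLE scaling (adjusted p = 0.0470), by fry in limma (0.0199) and in batch 2 alone (9.02e-04). In batch 2 alone it was also called higher in acd15 and acd15 acd21 sln (0.0212 each). Green tissue genes were called higher in batch 2 alone in sln (0.00172) and acd15 (0.00325) and with no low-count filter in acd15 (0.0428). They were called lower in batch 1 alone in acd15 acd21 (0.0353) and acd15 acd21 sln (6.07e-06). Of the lists without a set test, FWA was the 1 called methylation-silenced gene in every mutant. Its fellow list member QQS had log2 changes of -0.08 to 0.08, SDC had 0 or 1 counts in every library, and the tapetum gene MYB80 (-0.01 to 0.77) and the floral organ gene PI (0.40 to 0.99) were not called.

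For some uncalled lists the direction of the camera test differed in sign from the median or mean of log2 changes. In mbd5 mbd6 this held for the methylation machinery (lower by the test, median 0.03, mean 0.01), DNA damage genes (lower, 0.04 and -0.02) and vegetative cell genes (lower, -0.02 and 0.01). DNA damage genes were lower by the test with a median of 0.25 and a mean of 0.14 in sln, 0.20 and 0.12 in acd15, 0.11 and 0.10 in acd21, and -0.02 and 0.07 in acd15 acd21. In acd15 demethylation genes were lower by the test (median -0.01, mean 0.02), as were sperm genes (-0.01 and 0.00). In acd21 other MBD genes were higher by the test (0.04 and -0.01), green tissue genes higher (0.05 and -0.00) and vegetative cell genes lower (0.01 and 0.01). Demethylation genes were higher by the test in acd15 acd21 (-0.07 and 0.23) and lower in acd15 acd21 sln (-0.04 and 0.08), where post-transcriptional silencing genes were higher (-0.04 and 0.08) and sperm genes lower (0.02 and 0.02).

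The direct comparison of sln with mbd5 mbd6 asked whether loss of the J-domain protein and of the methyl-binding proteins have the same effect. AT1G67750 was 56.0-fold lower in sln than in mbd5 mbd6 (log2 -5.81 ± 0.07, adjusted p = 2.21e-45), the added transcript novel_Chr3_noncoding_1164 changed by -1.59 ± 0.05 and the transposable element AT3TE51735 by -2.44 ± 0.09. The level of novel_Chr3_noncoding_1164 was 66.6 ± 5.90 CPM in wild-type, 70.3 in sln and 211 in mbd5 mbd6. In all 155 features were higher in sln and 249 lower, with 7 higher and 30 lower transposable elements and 117 higher and 127 lower protein-coding genes. With DESeq2 the split was 93 higher and 282 lower. The 404 changed features became 221 without mbd5 mbd6 library 3, 246 without mbd5 mbd6 library 4, 264 without sln library 4 and 208 without sln library 5, and within batches 54 (batch 1) and 501 (batch 2) were changed.

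**Figure D4:**
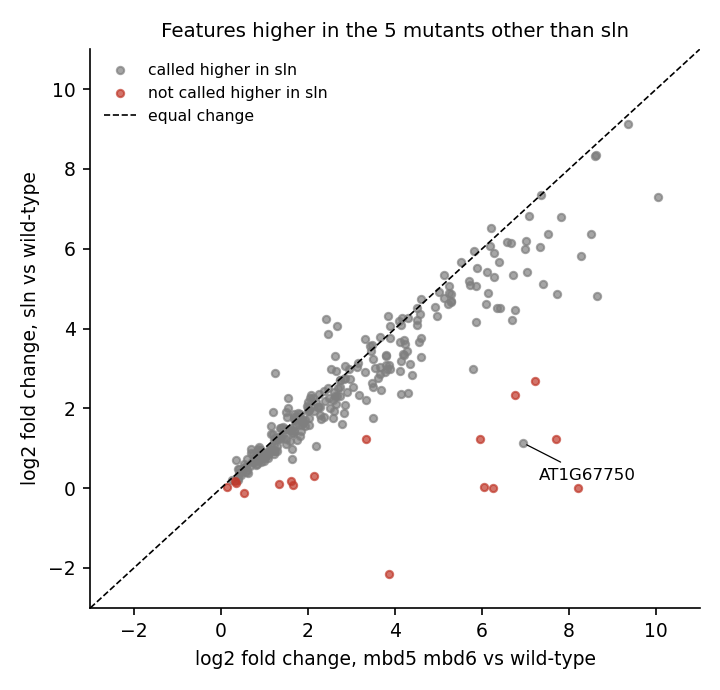
Log2 change against wild-type in sln (vertical axis) and mbd5 mbd6 (horizontal axis) of the 277 features called higher in the 5 mutants other than sln (edgeR, n = 5 per genotype). The 17 features not called in sln are red, and the other 260 were called higher in sln as well.

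Of the 277 features higher in the 5 mutants other than sln, 260 were called in sln and 17 were not. The 17 included SYP122, the beta-glucosidase gene BGLU21 (0.52 ± 0.13 in mbd5 mbd6), the kinesin gene AT4G39050 (0.33 ± 0.10), the protein kinase gene SOS2 of salt tolerance (0.15 ± 0.04), AT5G21900 (1.60 ± 0.13), AT1G67105 (2.13 ± 0.50), AT2TE03160 and novel_Chr3_noncoding_1164. In the test of the difference itself, 78 of the 277 were lower and 7 higher in sln than in mbd5 mbd6. Of the 17, which their missing call in sln selects for low values there, 14 were lower.

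The acd15 acd21 and acd15 acd21 sln mutants were compared with mbd5 mbd6 as a question of whether losing the alpha-crystallin proteins equals losing the methyl-binding ones. NAC105 was 147-fold lower in acd15 acd21 than in mbd5 mbd6 (log2 -7.20 ± 0.19, adjusted p = 1.03e-34), while the pseudogene AT1G43590 (chromosome 1, 16414121 to 16414627) was 2.70-fold higher (1.43 ± 0.09) and AT1G43270 5.70-fold higher (2.51 ± 0.18). There were 139 higher and 57 lower features, among them 25 higher and 2 lower transposable elements; within batches 58 and 132 were changed. Between acd15 acd21 sln and mbd5 mbd6, SLN (AT5G37380) changed by -4.02 ± 0.26, the transposable element AT4TE10320 by 0.97 ± 0.07 and the transporter gene UMAMIT41 (chromosome 3, 10442608 to 10445431) by -1.93 ± 0.14. Here 128 features were higher and 141 lower, with 11 and 15 transposable elements, and 71 and 202 were changed within batches 1 and 2.

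The single and joint acd mutants were compared to ask whether ACD15 and ACD21 act on different transcripts. Between acd15 and acd21, 34 features differed, 24 of them higher in acd15: the mannose-binding lectin gene AT5G49850 (chromosome 5, 20259440 to 20262585) was 3.56-fold higher in acd15 (log2 1.83 ± 0.08, adjusted p = 8.86e-23), AT1G35115 changed by 1.47 ± 0.08 and AT3G32425 by -0.81 ± 0.10. AT5G49850 was 38.2 ± 2.12 CPM in wild-type and lower in acd21 (-1.77 ± 0.08), with changes of 0.07 in acd15 and -0.07 in acd15 acd21 that were not called. Between acd15 acd21 and acd15, 17 features were higher and 12 lower, with AT1G43590 at 1.66 ± 0.09, AT5G15360 at 3.82 ± 0.24 and the aspartyl protease gene AT1G64830 at 3.21 ± 0.24. Between acd15 acd21 and acd21, 26 were higher and 7 lower, with AT5G49850 at 1.70 ± 0.08, AT1G43590 at 1.63 ± 0.09 and AT5G15360 at 4.07 ± 0.28. Transposable elements made up 6, 2 and 3 of the changed features. In batch 1 alone 3, 5 and 11 features were changed in these comparisons, and in batch 2 alone 14, 16 and 13.

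The addition of sln to acd15 acd21 was examined against both parents. Against acd15 acd21, NAC105 was 149-fold higher in acd15 acd21 sln (log2 7.22 ± 0.19, adjusted p = 8.43e-35), AT1G43590 changed by -1.81 ± 0.09 and SLN (AT5G37380) by -4.06 ± 0.26, and 87 features were higher and 180 lower, with 4 and 22 transposable elements (60 and 113 changed within batches 1 and 2). Against sln, AT1G67750 was 63.1-fold higher (5.98 ± 0.07, adjusted p = 7.01e-46), novel_Chr3_noncoding_1164 rose by 1.85 ± 0.05 and AT3TE51735 was 8.01-fold higher, and 359 features were higher and 214 lower, with 26 and 15 transposable elements. With RLE scaling that split was 536 and 195, and with DESeq2 666 and 132. The 573 changed features became 196 without sln library 5, 990 without triple mutant library 1, 368 without triple mutant library 2 and 303 without triple mutant library 4, and 51 and 609 within batches 1 and 2.

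Interaction terms asked whether effects of the mutations add on the log2 scale. For acd15 by acd21, AT1G67750 departed from additivity by -7.31 ± 0.10, AT3TE51735 by -9.15 ± 0.20 and AT3G31470 by -4.20 ± 0.11; of AT3G31470, the changes against wild-type were 4.22 in acd15, 4.21 in acd21 and 4.23 in acd15 acd21. In all 400 features departed, 325 below and 75 above the sum, 66 and 7 of them transposable elements. For sln by acd15 acd21, AT3G31470 departed by -4.28 ± 0.11, AT4G07498 by -4.33 ± 0.12 and the transposable element AT4TE21020 by -2.62 ± 0.09, among 674 features with 453 below the sum and 221 above it. With DESeq2 the latter split was 388 below and 422 above, and with batch 1 alone 174 and with batch 2 alone 384 features departed.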

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

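The tests of a wrong label, of a common shift and of a linked region for sln, of the relation of noncoding features and of transposable elements below the filter to reads in no feature, and of replicate 4 among the batch 2 libraries, and the counts of splits by batch, were chosen after the result was seen.

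Of the 277 features higher in the 5 mutants other than sln, 17 were not called in sln, SYP122 and AT2TE03160 among them. That the sln libraries came from pollen with wild-type SLN levels is excluded. SLN in the highest sln library stood at 12.0% of the lowest wild-type library. SLN was also low in acd15 acd21 sln, so these counts cannot exclude an exchange of labels between these genotypes. That 1 linked chromosome region carried by the 5 mutants holds all 17 features is excluded. At most 2 of the 10 features with a position lay within 2 Mb of each other, and the 10 lay on 4 chromosomes. The features without a position, several of them on chromosome 2 by their identifiers, could not be tested for a shared region. A common shift of every shared feature in sln is excluded too, because 112 of the 277 (40.4%) departed from the common difference, 67 below it and 45 above. A weaker sln allele stays open as far as the median goes, which was -0.23 over the 277 (quartiles -0.68 and -0.02) and lay between the bounds set for and against it, while the departures above argue against an equal lowering of all features. That SLN is dispensable for some targets of MBD5 and MBD6 is the hypothesis of a biological difference, and no test here tells it from an allele with remaining function; libraries of another sln allele, in which the 17 features were again not higher, would argue against the latter, and none were analysed here.

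The mean level of 1161 noncoding features that no comparison called moved with the percentage of reads in no feature over the 35 libraries, genotype and batch means removed (Pearson's r = 0.915, Spearman's rho = 0.922, permutation p = 1e-05, the smallest possible, adjusted 2e-05 over 4 relations). Within batches r was 0.954 and 0.838, and without the 2 libraries farthest from the median 0.892. Genomic DNA in the libraries stays open: the share of nuclear genes below the filter argues against it, with r = 0.0397 (permutation p = 0.821) and a 95% interval of -0.297 to 0.368 that ends below the r expected of genomic DNA but above the bound set against it, while that of transposable elements below the filter goes with it and rose with the percentage (r = 0.769, rho = 0.758, permutation p = 1e-05, 0.907 and 0.60 within batches). Wrong-strand reads of abundant genes may be 1 source: over 48 noncoding genes antisense to a tested protein-coding gene, the slope on the percentage rose with the level of the opposite gene (Spearman's rho = 0.744, permutation p = 1e-05, the smallest possible), and rho was 0.739 with the own level of the antisense gene removed. That permutation shuffled genes, whose slopes come from the same 35 libraries, so its p does not measure the spread between libraries. No biological explanation was tested, since the relation holds within genotypes.

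Heat shock genes were highest in replicate 4 among the 3 batch 2 libraries in 6 of 7 genotypes. A condition shared by those libraries stays open, since list and replicate were picked for this pattern: with the batch 2 libraries shuffled within genotypes, as many genotypes came up for some replicate and some of the 11 lists with permutation p = 0.197. Leaf or stem tissue in them stays open, since the relation of the heat shock and green tissue lists had a wide interval (r = 0.102, 95% interval -0.24 to 0.421, permutation p = 0.564). Whether the replicate 4 libraries lie behind the lower heat shock list in mutants stays open: without them the list was still called lower by camera in limma in 2 of the 3 mutants, sln (adjusted p = 0.0487) and acd15 acd21 sln (0.00523), and not in mbd5 mbd6 (0.162), with medians of -0.37, -0.59 and -0.81 in mbd5 mbd6, sln and acd15 acd21 sln. With all libraries these medians were -1.28, -1.29 and -1.46 and adjusted p = 0.777 with an estimated correlation for all 3.

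A gap of 1 library from the other 4 of its genotype was found in 5 of 105 groups of libraries and measures, where chance gives about 1 in 20 groups. In mbd5 mbd6 library 2 the organelle share was 0.0435% of counts, the mean log2 level of the DNA demethylation genes 0.87 and that of the heat shock genes 1.85. The total of sln library 5 was 22.2 (in units of 1e6 counts), and the mean log2 level of the green tissue genes in acd15 acd21 library 1 was 1.15.

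Tests of a difference of effects between batches called 1 feature for mbd5 mbd6, AT3G31475 (1.03 ± 0.19, adjusted p = 0.0437 in edgeR), and 1 for acd15 acd21 sln, AT4G35100 (4.57 ± 0.77, adjusted p = 0.00977). Both were named after their values were seen. AT3G31475 had uncalled differences of 0.91, 0.98, 0.90 and 0.96 in sln, acd15, acd21 and acd15 acd21 (adjusted p = 0.0875 to 0.312 in edgeR). Its difference is thus not particular to mbd5 mbd6, and all these tests share the wild-type libraries. The effect of acd15 differed with and without acd21 for 400 features, and the effect of sln with and without acd15 acd21 for 674. The share of counts in transposable elements below the filter, which no comparison used, was 0.00617% in wild-type, 0.00742% in sln, 0.00795% in acd15 and 0.00745% in acd21 (exact permutation p = 0.0476, 0.0238 and 0.0159, adjusted 0.0857, 0.0714 and 0.0714), so that none passed adjustment. In mbd5 mbd6, acd15 acd21 and acd15 acd21 sln it was 0.00752, 0.00751 and 0.00622% (exact permutation p = 0.0714, 0.0635 and 0.929), and over the libraries it moved with the percentage of reads in no feature (r = 0.769).

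For every count of changed features, 100 splits of the same libraries, the real one included, were fitted with only those libraries. All 16 counts passed the bound set before, under 5 of 100 splits with as many. Where only the real split gave as many, the counts were rare among the splits by this bound, the interactions aside. Many splits unbalance the batches, unlike the genotypes. Balanced ones numbered 46 to 51 in each of these comparisons, and only the real one gave as many (1.96 to 2.17%, not adjusted over comparisons). Chance is therefore not fully excluded. The 3 comparisons among the acd mutants passed the same bound, but chance is not excluded for them, since other splits called more features than the genotypes. Against wild-type the real and the highest other count were 565 and 256 for mbd5 mbd6, 519 and 374 for sln, 544 and 18 for acd15, 451 and 98 for acd21, 430 and 273 for acd15 acd21, and 427 and 192 for acd15 acd21 sln; only the real split, 1 of 100, gave as many. The same held for sln against mbd5 mbd6 (297 and 112), acd15 acd21 and acd15 acd21 sln against mbd5 mbd6 (166 and 160, 167 and 139), acd15 acd21 sln against acd15 acd21 (177 and 56) and sln (144 and 13), and the interactions acd15 by acd21 (396 and 97) and sln by acd15 acd21 (457 and 3). Splits of the interactions shuffled all genotype labels, which also removes the effect of each mutation by itself. They therefore cannot tell whether the departures from additivity arose by chance. For acd15 against acd21 the counts were 42 and 140 (2 of 100 as large), for acd15 acd21 against acd15 23 and 45 (3 of 100), and for acd15 acd21 against acd21 26 and 208 (3 of 100). Of the splits drawn with 2 batch 1 libraries in each arm, as in the genotypes, 1 of 47, 2 of 46 and 1 of 44 gave as many in these 3 comparisons, the real one included, with 11, 45 and 4 as the highest other. The splits with 140 and 208 calls put all 4 batch 1 libraries in 1 arm, with acd15 library 4 or acd15 acd21 library 5. With a batch term such a contrast rests on that library against the other batch 2 libraries. The 4 splits of this kind drawn in each of the 2 comparisons had medians of 0 and 4 calls, so that the placement of batch 1 alone did not give as many. What sets these libraries apart was not tested. In batch 2 alone the real comparisons called 14, 16 and 13 features and in batch 1 alone 3, 5 and 11.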

How the results depend on the processing

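The fits with the percentage of reads in no feature as a covariate, without replicate 4 libraries, without the 3 libraries apart on the second principal component, without the 3 libraries with the lowest percentage of reads in no feature, and with estimateDisp dispersions were chosen after the data were seen. Under every alternative the 6 comparisons with wild-type had more higher than lower features, except acd15 acd21 sln without its library 1 (500 higher, 519 lower), and transposable elements were 12.4 to 24.9% of higher features. With RLE scaling, DESeq2 and estimateDisp no count against wild-type and no total of changed features moved by over 1.5 times, though with DESeq2 the higher features became 93 in place of 155 for sln against mbd5 mbd6 and 422 in place of 221 in the sln interaction, and for acd15 acd21 sln against sln 666 were higher and 132 lower in place of 359 and 214. Under these 3 alternatives 187, 185 and 187 results of named features kept their side of the threshold while 1, 3 and 1 lost a call; 41 calls were lost in batch 1 alone, 17 in batch 2 alone, 10 with no batch term, 10 without replicate 4 libraries and 5 with no filter. Where counts moved, the cause was not tested, except that a 2-fold minimum calls fewer features by construction. Fewer libraries did not always call fewer: without library 1 of acd15 acd21 sln its lower features rose from 289 to 519.

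Values are given in the order mbd5 mbd6, sln, acd15, acd21, acd15 acd21, acd15 acd21 sln. With batch 1 alone 223, 192, 272, 262, 252 and 250 features were higher and 29, 18, 31, 37, 25 and 100 lower than in wild-type. Changed features were 54 for sln, 58 for acd15 acd21 and 71 for acd15 acd21 sln against mbd5 mbd6, 3 for acd15 against acd21, 5 and 11 for acd15 acd21 against acd15 and acd21, 60 and 51 for acd15 acd21 sln against acd15 acd21 and sln, and 214 and 174 for the interactions acd15 by acd21 and sln by acd15 acd21. With batch 2 alone 109 features were lower in sln, 98 in acd21 and 248 in acd15 acd21; 14, 16 and 13 were changed among the acd mutants, 113 between acd15 acd21 sln and acd15 acd21, and 384 in the sln interaction, and 20 list tests were called in place of 11.

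With a 2-fold minimum 271 features were higher in mbd5 mbd6, 277 in sln, 295 in acd15 acd21 and 275 in acd15 acd21 sln, and 29, 26, 23, 22, 45 and 70 were lower. The comparisons between mutants, in the order above, then had 93, 62, 67, 14, 12, 12, 64 and 92 changed features and the sln interaction 308. With only the groups compared in the fit, 379 features were higher in sln and 284 in acd15 acd21 sln, 99 and 143 lower in acd15 acd21 and acd15 acd21 sln, and 167, 177 and 144 changed in acd15 acd21 sln against mbd5 mbd6, acd15 acd21 and sln. Without replicate 4 libraries 115 features were lower in sln and 94 in acd15 acd21, and 217 changed for sln against mbd5 mbd6, 20 for acd15 against acd21, 227 for acd15 acd21 sln against sln and 426 in the sln interaction. With the no-feature covariate 186 features were lower in acd15 acd21 sln; without the 3 libraries apart on the second principal component (mbd5 mbd6 2, acd15 acd21 1, acd15 acd21 sln 2) also 186, and 177 changed against mbd5 mbd6. Without the 3 libraries with the lowest no-feature percentage 176 changed between acd15 acd21 sln and acd15 acd21. With no batch term 263 features changed for sln against mbd5 mbd6 and 340 for acd15 acd21 sln against sln. With no low-count filter 55, 45 and 64 features changed among the acd mutants. With an estimated correlation 6 list tests were called. The similarity of mutants was 0.912 with wild-type libraries split and 0.907 over all features, where unchanged groups gave 0.509 and split wild-type libraries 0.808.

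Leaving out each library in turn gave 417 to 526 higher features in mbd5 mbd6, 400 to 651 in sln, 407 to 443 in acd15, 371 to 398 in acd21, 405 to 459 in acd15 acd21 and 400 to 500 in acd15 acd21 sln. Lower features ranged over 117 to 205, 90 to 256, 94 to 117, 104 to 143, 107 to 198 and 194 to 519; 90 came without sln 5 and 519 without acd15 acd21 sln 1. Changed features were 208 to 561 for sln, 158 to 184 for acd15 acd21 and 200 to 375 for acd15 acd21 sln against mbd5 mbd6, 24 to 34 for acd15 against acd21, 23 to 33 and 23 to 32 for acd15 acd21 against acd15 and acd21, 192 to 264 and 196 to 990 for acd15 acd21 sln against acd15 acd21 and sln, and 385 to 426 and 477 to 890 for the interactions. For sln against mbd5 mbd6 the count was 221 without mbd5 mbd6 3, 246 without mbd5 mbd6 4, 264 without sln 4 and 208 without sln 5, and for acd15 acd21 sln against sln 196 without sln 5, 990 without acd15 acd21 sln 1, 368 without acd15 acd21 sln 2 and 303 without acd15 acd21 sln 4. Transposable elements were 15.8 to 17.3, 12.4 to 19, 19.5 to 21.2, 19.1 to 20.9, 19.0 to 21.5 and 14.8 to 18.3% of higher features. Over all such fits the named features kept their side of the threshold 1870 times and lost a call 70 times, and no direction reversed.

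Replicates share numbers across genotypes, but over all tested features correlations of libraries with the same number had both signs. Those of 105 pairs ran from -0.456 to 0.416, 16 of them above 0.1, and 7 of 35 libraries correlated best with their own number. Heat shock genes, however, were highest in replicate 4 of batch 2 in 6 of 7 genotypes. With the number as a replicate block 524, 614, 447, 416, 488 and 489 features were higher and 225, 289, 139, 176, 186 and 290 lower. Between mutants 472, 210, 314, 36, 37, 41, 320 and 748 changed, and 425 and 894 in the interactions, and 12 list tests were called. None of these moved by over 1.5 times, but all lay above the counts of the main fit. Variation shared by libraries with the same number is therefore not excluded. The block added calls of HSP101 in mbd5 mbd6 (adjusted p = 0.0211) and sln (0.0477) and of the heat shock list in acd15 acd21 (0.0400), ended that of novel_Chr3_noncoding_1248 (0.0565), and changed no other call of a named feature or list. Low counts limit what can be said of the targeted genes MBD5, ACD15.5 and ACD21.4, with at most 4 counts per library, and of most transposable elements, of which 258 of 23488 could be tested and 2866 had any count. Whether depth, silence or the handling of multi-mapping reads lies behind this was not tested.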

Other observations

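Some features separated mutants that otherwise shared most of their higher features. The transporter gene UMAMIT41 was 2.49 ± 0.59 CPM in wild-type and 7.18 ± 0.68 in mbd5 mbd6, a log2 change of 1.52 ± 0.13, but 1.56 ± 0.25 CPM in sln, a change of -0.68 ± 0.18 (SD of CPM, n = 5; both called in edgeR); sln differed from mbd5 mbd6 by -2.20 ± 0.14 (adjusted p = 1.66e-16). AT1G35115 stood at 19.7 ± 1.5 CPM in acd21, where it was not called (log2 0.12), and at 54.6 ± 5.3 in acd15 (log2 1.59). The added transcript novel_Chr5_coding_282 followed NAC105 in being lower in acd15, acd21 and acd15 acd21, at 0.339, 0.344 and 0.252 CPM against 1.60 in wild-type, but was at 1.70, 1.55 and 1.70 CPM in mbd5 mbd6, sln and acd15 acd21 sln, where it was not called. The difference of acd15 acd21 from mbd5 mbd6 was -2.67 ± 0.28 (adjusted p = 2.72e-09 in edgeR) and that of acd15 acd21 sln from acd15 acd21 2.64 ± 0.29 (adjusted p = 6.76e-09).

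The pseudogene AT1G43590 was higher in acd15 acd21 (1.18 ± 0.08) and lower in acd15 (-0.47) and acd21 (-0.44), as well as in sln (-0.77) and acd15 acd21 sln (-0.63). The aspartyl protease gene AT1G64830 was lower in acd15 (-1.83) and higher in acd15 acd21 (1.38), from 1.3 ± 0.36 CPM in wild-type. AT5G15360, with 0 counts in wild-type and 1 in sln, had 120 counts over the mbd5 mbd6 libraries and 246 over the acd15 acd21 libraries, but 19 in acd15, 11 in acd21 and 14 in acd15 acd21 sln. AT5G49850 fell in acd21 and not detectably in acd15 acd21, whose label names the same gene. No explanation of these patterns was tested.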
